A study of Mus musculus with 12 samples.

How the data were processed

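RNA was measured on 12 Illumina MouseWG-6 arrays, 3 from each of 4 groups: ependymal cells sorted from the adult lateral ventricular wall (LVW) and spinal cord (SC), radial glia sorted at embryonic day 14.5, and neurospheres grown from SC ependymal cells. Per the labels' protocols, the arrays of a group are independent biological replicates, and total RNA was amplified in 2 rounds and labelled with biotin. BeadStudio and lumi are named per the submitters' processing notes. Per the file headers, the deposited raw table holds an intensity for each of 46632 probes on each array, and the values go below 0, as signals do after background subtraction. It also holds, per the file headers, a detection p-value of each probe on each array. Steps in those p-values showed 1509 negative controls behind neurosphere replicate 3 and 1603 behind the other arrays. The authors' processed table is on a log2 scale and was quantile normalised between arrays. The sorted values of all 12 arrays matched those of the first within 0.001, and 2 probes were empty.

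The raw intensities were used. They were background corrected with limma 3.58.1 (neqc in R 4.3.3), with the mean and SD of the negative controls inferred from the detection p-values and an offset of 16, then quantile normalised and taken to log2. A probe was kept when its detection p-value was under 0.01 on at least 3 of the 12 arrays, which left 15760 probes. Of all probes, 29976 had 1 gene symbol, 10 had several and 16646 had none, and 12211 kept probes had a symbol. Each gene was represented by its kept probe of highest mean over all arrays, which gave 9526 genes of 17711 named on the array. A gene counted as detected on an array when this probe was. Where the lower group detected a gene on 0 arrays, a fold is given as a bound, and list medians are also given with such genes at their bounds and genes detected in neither group at 0. The bound sets the higher group's mean log2 signal against the lower group's mean of, per array, the weakest detected signal or the probe's own signal if that is higher. Where only some arrays of the lower group detected a gene, its change includes arrays below detection. Probes without a symbol were not analysed here.

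A linear model with 4 groups was fitted to the 12 arrays with limma (lmFit and eBayes, two-sided), and 5 comparisons were drawn from it. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called when its adjusted p was under 0.05. The 12 arrays share 1 estimate of spread per gene. The SD of log2 differences between 2 arrays was 1.23 to 1.44 within LVW and 0.61 to 0.77 within radial glia. The shared estimate can thus make standard errors and p-values of comparisons with LVW too small. Changes are log2 differences with the model's standard error, and levels are group means with the standard deviation. The comparisons, tests, 22 gene lists and all but 2 of the alternatives were chosen before the data were examined. The lists hold 554 genes, counted once, of which 353 were tested. They cover cilia and ependymal markers, regional transcription factors, cell cycle and stem cells, other cell types of the tissue, signalling pathways, metabolism and antigen presentation. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 22 lists of a comparison. Genes were also adjusted over the list alone.

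Genes were named by a rule set at the same time: the genes of the sort antigens, the 6 largest changes in each direction that were called, did not overlap between groups and were detected throughout the higher group, and up to 4 called members of each list. Where 5 or fewer members of a list were called in a direction and named beyond this rule, they were chosen after their values were seen. Overlaps of 2 comparisons were set beside the overlap of independent lists and beside 50 simulations of unchanged groups that used the same shared arrays. Other lists and gene families were chosen after the comparisons had been seen, and they are given with the other observations. Their medians were set beside 10000 random lists drawn from 20 bins of mean expression, with intervals from 10000 bootstrap draws.

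The alternatives tried were 2 other background corrections (none, with signals floored at 1, and normexp without controls with an offset of 50), median scaling, the authors' values, 2 other probe filters, the mean over probes, a further threshold of a log2 change of 1, array weights, the replicate number as a block, a fit to the 6 arrays compared, and leaving out each array. Replicate numbers are not stated to link samples across groups, so no pairing was used. The method was also tested on simulated data with the spread of these arrays. In 20 draws with 200 changed genes, between 47.5% and 51.7% of 4-fold changes and between 84.1% and 85.6% of 8-fold changes were recovered, but only 2.31% to 3.36% of 2-fold changes. The real comparisons called 766 to 3473 genes, and the adjustment admits larger p-values where more genes change. These shares thus hold for 200 changed genes and do not give the recovery in the real comparisons.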

Results

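Gene expression was measured on Illumina mouse bead arrays in 4 groups of cells from C57Bl/6 mice. Ependymal cells line the brain ventricles and the central canal of the spinal cord, and many of them carry cilia that move cerebrospinal fluid. They were sorted from the lateral ventricular wall (LVW) and the spinal cord (SC) of adult mice as cells positive for CD133 and CD24 and negative for CD45 and CD34. Radial glia, the neural stem cells of the embryo, were sorted at embryonic day 14.5 as cells positive for CD133 and negative for CD24, CD45 and CD34. Neurospheres, floating balls of dividing cells, were grown in culture from SC ependymal cells and were not sorted. Each group had 3 arrays, and this number limits the precision of every comparison.

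Of the 46632 probes, the LVW ependymal arrays detected 11660, 12132 and 11755, and the SC ependymal arrays 10742, 12298 and 11793. The radial glia arrays detected 13487, 12273 and 12824, and the neurosphere arrays 11434, 11674 and 16175. Mean raw signal lay between 349.5 and 405 in LVW, between 170 and 194 in SC and between 360 and 375 in radial glia. It was 199, 248 and 654 in the neurosphere arrays. Across the 9526 genes tested, which are not independent replicates, the mean profiles of the 2 ependymal groups correlated at r = 0.895. Neurospheres correlated with radial glia at 0.820 and with SC ependymal cells at 0.736. Radial glia correlated with SC and LVW ependymal cells at 0.717 and 0.676. Among single arrays, neurosphere replicates 1 and 2 were the closest pair of all (r = 0.973), while each correlated with replicate 3 at 0.895 and 0.869. Arrays within LVW correlated at 0.836 to 0.876, within SC at 0.920 to 0.946 and within radial glia at 0.950 to 0.968.

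The genes behind the sort antigens were read first. Prom1, which encodes CD133, was high in all 9 arrays of sorted cells, with mean log2 levels of 13.32 ± 0.32 (SD, n = 3) in LVW, 11.74 ± 0.11 in SC and 13.51 ± 0.11 in radial glia. Neurospheres had 9.40 ± 0.44, which was lower than SC by 2.33 ± 0.30 (SE; adjusted p = 0.000125). Cd24a was detected on all 3 LVW arrays, on 1 SC array and on 0 radial glia arrays, in which it was at least 6.82-fold lower than in LVW. Between SC and LVW, Prom1 was lower in SC (-1.59 ± 0.30, adjusted p = 0.00713), and so was Cd24a (-2.63 ± 0.50, adjusted p = 0.00725). The Cd24a difference was no longer called in a fit to the 6 arrays alone (adjusted p = 0.103) or without background correction (0.0525). With only SC replicate 1 kept in that group, neither Prom1 (adjusted p = 0.184) nor Cd24a (0.128) was called. No kept probe represented Ptprc, which encodes CD45, or Cd34.

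**Figure D1:**
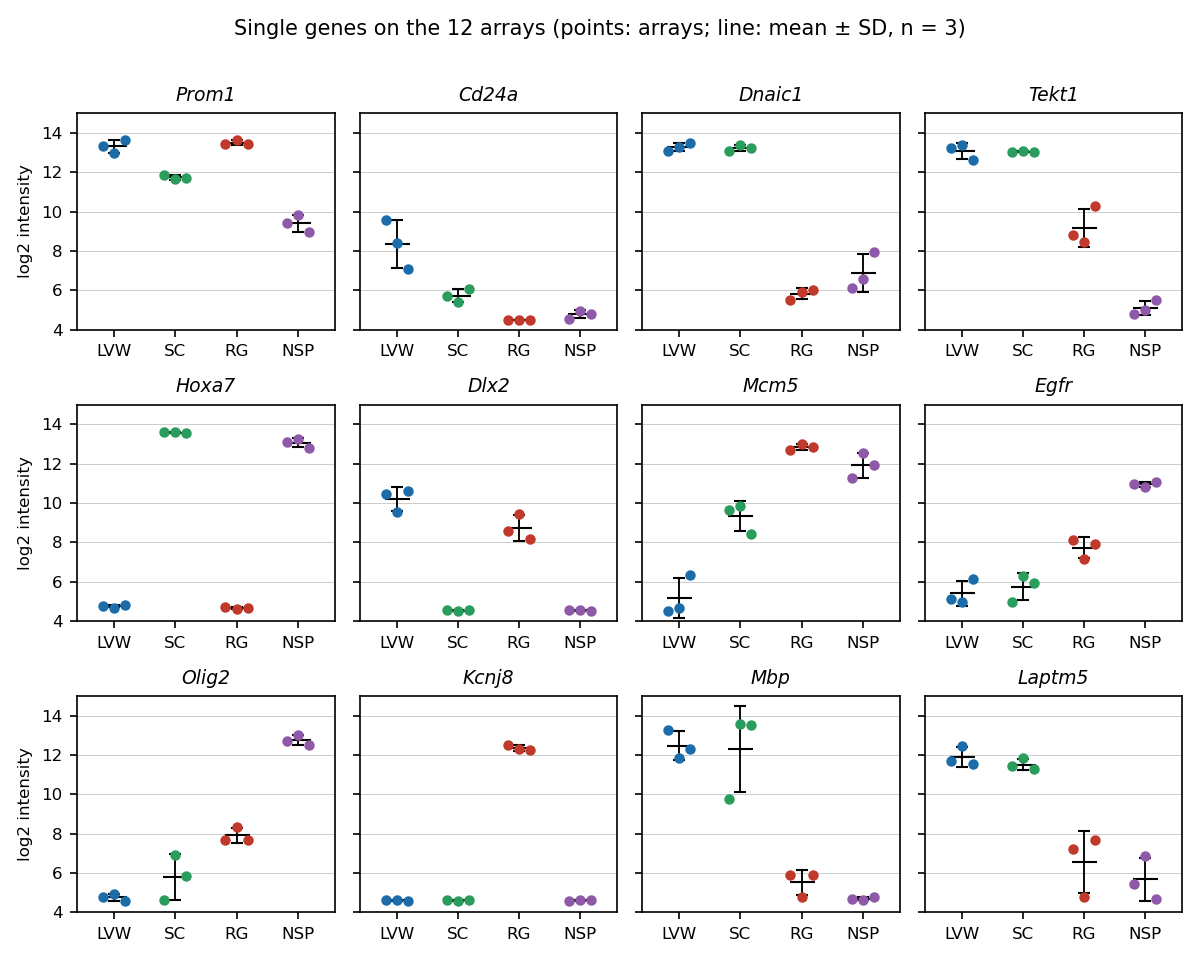
Normalised log2 intensity of 12 genes on each array (points), with the mean and SD of each group of 3 arrays (bars). Cilia genes Dnaic1 and Tekt1 were high in both ependymal groups, Hoxa7 in SC ependymal cells and neurospheres, and Kcnj8 in radial glia.

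The first comparison asked how ependymal cells of the spinal cord differ from those of the lateral ventricular wall. The clearest differences were in regional transcription factors. Hox genes, which pattern the trunk along the body axis, were higher in SC: 15 of the 20 tested were called, and 17 adjusted over the list alone. Hoxa7 was at least 211-fold higher (n = 3 per group) and was detected on 0 LVW arrays. Hoxc6 was at least 128-fold and Hoxa5 at least 109-fold higher. Nkx6-1, a ventral neural tube factor, was at least 65.0-fold higher. In the other direction, 5 of 17 forebrain transcription factors were lower in SC and 9 adjusted over the list alone. Among them, Dlx2 was at least 19.1-fold, Otx1 at least 7.26-fold and Dlx1 at least 3.43-fold lower. The factor Nr2f1 was higher by 1.57 ± 0.40 (SE) on the log2 scale, but was not called with LVW replicate 2 or 3 or any 1 SC array left out (adjusted p between 0.0696 and 0.121). The median change was 4.99 for Hox genes and -1.03 for forebrain factors. With genes undetected in one group set at their bounds, these medians were 3.68 and -0.11. The camera list test called both lists (adjusted p = 4.89e-28 and 0.000424). Both calls held with an estimated correlation (adjusted p = 0.00106 and 0.024).

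In all, 766 of 9526 genes differed between the ependymal groups, 294 higher and 472 lower in SC. The count was 487 without LVW replicate 1, 485 without SC replicate 2 and 475 without SC replicate 3, and it was 292 in a fit to the 6 arrays alone. Motile cilia genes had a median change of -0.05, and the camera test did not call them (adjusted p = 0.794). The largest decreases in SC were in single genes of varied function. Ces1d, a carboxylesterase, was at least 53.1-fold lower, and Cyp4f15, which oxidises fatty acids, at least 49.6-fold. Hp, which encodes the haemoglobin scavenger haptoglobin, was at least 44.3-fold lower. The crosslinking enzyme gene Tgm2 fell by 6.19 ± 0.40 and the zinc transporter gene Slc39a4 by 6.05 ± 0.75 (detected on 2 SC arrays), and the actin-severing gene Scin was at least 23.6-fold lower. Of the glycolysis and hypoxia list, the carbonic anhydrase gene Car9 was at least 20.4-fold lower.

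BMP and TGF-beta pathway genes were also lower in SC, with 7 of 21 called and 7 adjusted over the list alone. Bmp6 was at least 8.98-fold lower, while Tgfb3 fell by 3.04 ± 0.46, which was not called with SC replicate 1 alone in its group (adjusted p = 0.117). The list test was called with the preset correlation (adjusted p = 0.0112) and lost with an estimated correlation (adjusted p = 0.232). Without LVW replicate 1 the list had 2 lower genes. It had 4 without LVW replicate 2 or SC replicate 1, and 3 without SC replicate 2 or 3. Cell cycle genes were higher in SC, with 5 of 33 called (Kif23, Mcm5, Prc1, Ccnd1 and Foxm1) and 8 adjusted over the list alone. Mcm5, which encodes a DNA replication factor, was higher by 4.17 ± 0.54, and Kif23, which acts in cell division, by 4.79 ± 0.75. Kif23 was not called in a fit to the 6 arrays alone (adjusted p = 0.059) or with SC replicate 1 alone in its group (0.102). LVW detected Mcm5 on 1 array and Kif23 on 2, and SC detected Tgfb3 on 1. The median of the cell cycle list was 0.69 and 0.30 with bounds (adjusted p = 0.00284), and the call was lost with an estimated correlation (adjusted p = 0.613). Without SC replicate 3, 3 cell cycle genes were called. The astrocyte list was lower in SC, with a median of -0.91, but 1 of 16 genes was called lower (Atp1b2, -1.52 ± 0.38), and 4 were lower and 1 higher adjusted over the list alone. Atp1b2 was not called without LVW replicate 1 or 3 or any 1 SC array (adjusted p between 0.0643 and 0.0968). The list call (adjusted p = 0.0337) was lost with an estimated correlation (adjusted p = 0.53). The median, the mean and the test did not share a sign for microglia, choroid plexus, Wnt and glycolysis lists, and none of these was called. Median scaling moved the median change of all genes from 0.05 to 0.18, against which these changes can be read.

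Markers of other cells differed between the ependymal groups in single genes. Fa2h, a gene of myelin lipids, was at least 4.83-fold higher in SC, and the matrix gene Vtn at least 13.2-fold. Dcn, which fibroblasts express, was at least 4.98-fold higher. Slco1c1, a transporter of brain vessels and astrocytes, was at least 8.28-fold lower. Of 11 choroid plexus genes 3 were lower, and 3 adjusted over the list alone, while the list was not called (adjusted p = 0.248). Clic6 fell by 5.36 ± 0.72 (detected on 2 SC arrays), and Sostdc1 was at least 8.70-fold and Otx2 at least 3.58-fold lower. Otx2 was not called without LVW replicate 1 or 3 or any 1 SC array (adjusted p between 0.0939 and 0.126). Myelin genes were uneven among the SC arrays. Mbp had log2 levels of 9.78, 13.56 and 13.55 on SC replicates 1, 2 and 3, and Mag had 4.63, 11.15 and 10.75. The oligodendrocyte list had 1 called gene, Fa2h, and 5 without SC replicate 1.

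**Figure D2:**
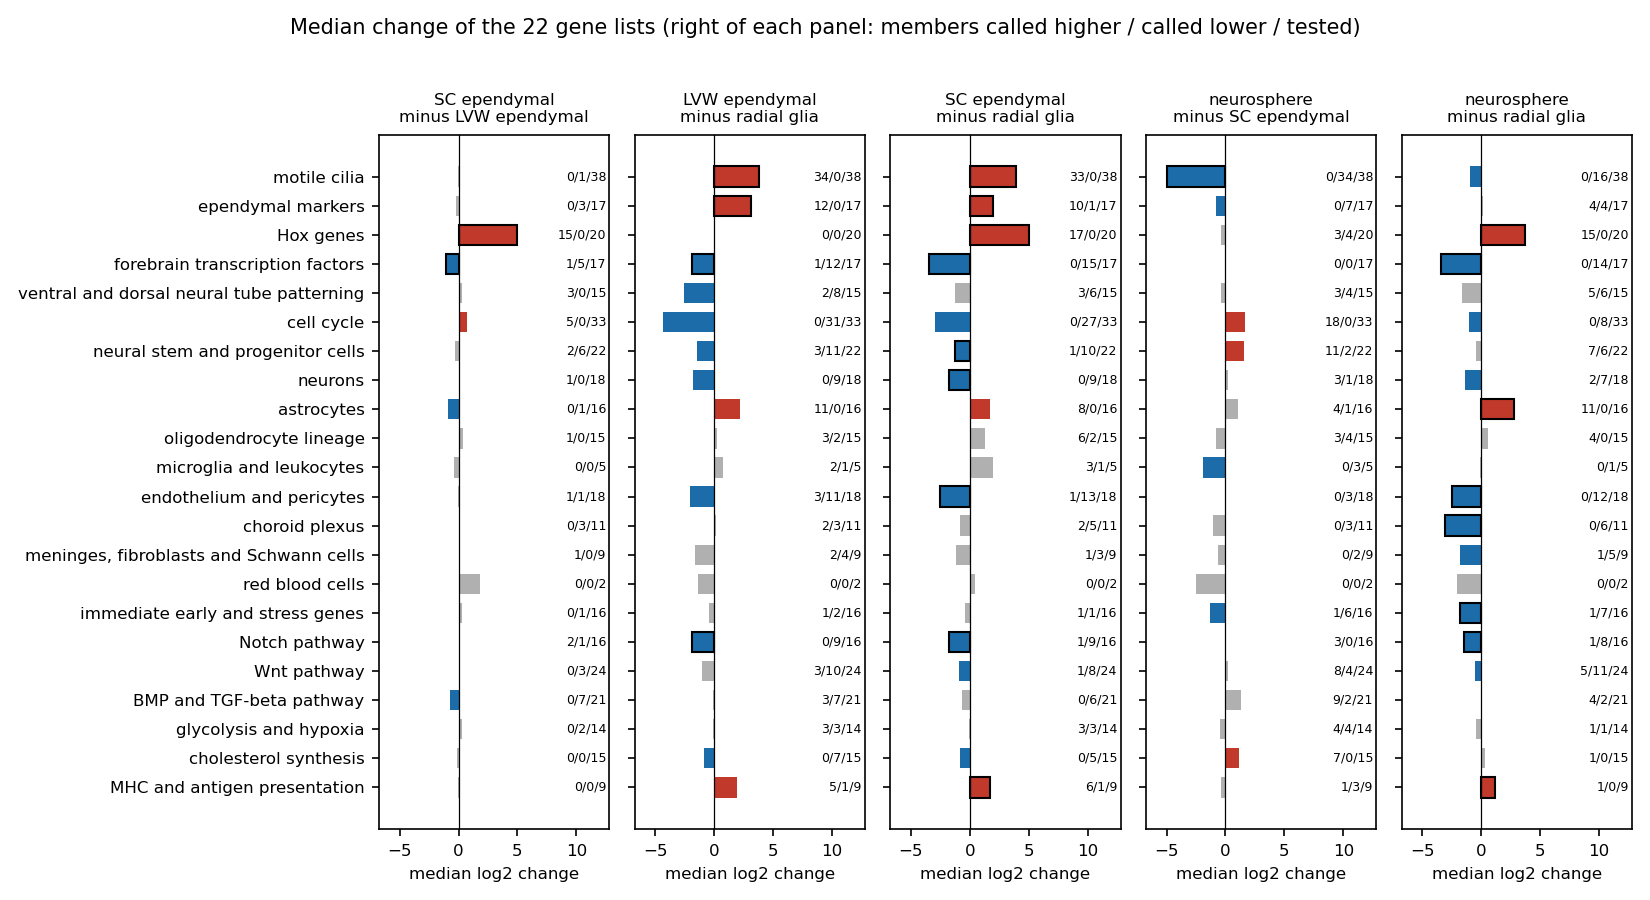
Median log2 change of the 22 gene lists in the 5 comparisons (bars), with the number of genes called higher, called lower and tested beside each bar. Red and blue bars were called higher and lower by camera and grey bars were not called, and a black edge marks a call that held with an estimated correlation.

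The next comparisons asked how the ependymal cells of each region differ from embryonic radial glia. The groups also differ in age and in the CD24 gate, and SC differs in region. Motile cilia genes were higher almost throughout: 34 of 38 were higher in LVW than in radial glia and 33 of 38 in SC, and 37 in each adjusted over the list alone. Dnaic1, which encodes an arm of the ciliary motor, was higher by 7.48 ± 0.42 in LVW and by 7.41 ± 0.42 in SC (SE, n = 3 per group). Fam183b was higher by 6.13 ± 0.47 and 6.58 ± 0.47. The list medians were 3.82 and 3.92 (3.74 and 3.86 with bounds), with camera adjusted p = 2.39e-22 and 3.7e-24. Both held with an estimated correlation (adjusted p = 0.0188 and 0.00987). Ependymal markers followed, with 12 of 17 higher in LVW and 10 of 17 in SC. Adjusted over the list alone, 12 and 11 were higher. Mia was higher by 5.24 ± 0.60 in LVW and 5.60 ± 0.60 in SC. In SC 1 of these markers, Prom1, was lower (-1.77 ± 0.30). The marker list also holds Cd24a, for which the sort gates of ependymal cells and radial glia differ, so its change is no separate evidence. Gja1, Aqp4 and S100b are in the astrocyte list as well.

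Cell cycle genes were lower in the adult cells: 31 of 33 in LVW and 27 of 33 in SC, and 32 in each adjusted over the list alone. Mcm5 fell by 7.70 ± 0.54 in LVW, and Tk1, which acts in DNA synthesis, was at least 31.5-fold lower there. In SC, Birc5, which acts in mitosis, was at least 10.6-fold lower, and Top2a fell by 4.21 ± 0.67. LVW detected Mcm5 and SC detected Top2a on 1 array. The medians were -4.30 and -2.93, and -3.49 and -2.79 with bounds (adjusted p = 1.05e-13 and 9.08e-12). The calls were lost with an estimated correlation (adjusted p = 0.0717 and 0.0766). Stem and progenitor genes were lower too, 11 of 22 in LVW and 10 of 22 in SC, and 11 in each adjusted over the list alone. In the other direction, Id4, Slc1a3 and Sox2 were higher in LVW, of which only Slc1a3 was called without LVW replicate 1 or 2 or radial glia replicate 1 or 3, and Slc1a3 was higher in SC. Hes5, a Notch target, was at least 11.3-fold lower in LVW, and Id1 and Id3, which respond to BMP, fell by 4.86 ± 0.46 and 4.77 ± 0.37 in SC, which detected them on 1 and 2 arrays. The list medians were -1.43 and -1.28, and -1.35 and -0.55 with bounds (adjusted p = 0.0145 and 0.000981). With an estimated correlation the SC call held (adjusted p = 0.0307) and the LVW call was lost (adjusted p = 0.0717). Notch pathway genes were lower, 9 of 16 in each. Adjusted over the list alone, 10 were lower in LVW and 12 in SC. In SC 1 was higher, the ligand gene Dner (3.65 ± 0.44). Notch3 was at least 16.3-fold lower in LVW, and Heyl at least 19.8-fold lower in SC, and both are also genes of the mural cell list of the other observations. These list calls held with an estimated correlation (adjusted p = 0.026 and 0.0237).

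Genes of the embryonic forebrain and of neurons were lower in both ependymal groups. Forebrain transcription factors were lower for 12 of 17 in LVW and 15 of 17 in SC, and for 12 and 15 adjusted over the list alone. Eomes, a gene of neuron progenitors, was at least 15.8-fold lower in LVW, and Fezf2 at least 120-fold lower in SC. Dlx2 was higher in LVW (1.48 ± 0.38), but was not called without radial glia replicate 3 (adjusted p = 0.0508). The list medians were -1.90 and -3.46 (-1.62 and -2.11 with bounds), and both calls held with an estimated correlation (adjusted p = 0.0188 and 0.00224). Leaving out 1 radial glia array took genes detected on those 3 arrays below the filter. Then 11 factors were tested, with 6 lower in LVW whichever of the 3 was left out, and in SC 9 lower without replicate 1 and 8 without replicate 2 or 3. Of 18 neuronal genes, 9 were lower in each, and 9 adjusted over the list alone. Neurod2 was at least 23.7-fold lower in LVW and at least 22.3-fold lower in SC, and Dcx, a gene of migrating neurons, at least 12.4-fold and 11.6-fold. The neuronal list was called in both (adjusted p = 0.00122 and 0.00102). With an estimated correlation the SC call held (adjusted p = 0.038) and the LVW call was lost (adjusted p = 0.0561). Hox genes were higher in SC than in radial glia, 17 of 20 and 18 adjusted over the list alone, with Hoxa7 at least 255-fold higher. In LVW the Hox list had a median of 0.05 (adjusted p = 0.632). The neural tube patterning list was lower in LVW, with 8 of 15 lower and 2 higher (adjusted p = 0.014), and the Wnt list in SC, with 8 of 24 lower and 1 higher (adjusted p = 0.00381). Both calls were lost with an estimated correlation (adjusted p = 0.0717 and 0.0857). With 1 radial glia array left out, 21 Wnt genes were tested in SC and 4 or 5 were lower.

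Astrocyte genes were higher in the adult cells, 11 of 16 in LVW and 8 of 16 in SC. Adjusted over the list alone, 11 and 9 were higher. Ntsr2 was at least 19.1-fold higher in LVW and at least 13.4-fold higher in SC. The list was called in both (adjusted p = 3.82e-05 and 0.000981), and lost with an estimated correlation (adjusted p = 0.0717 and 0.146). In SC, 5 astrocyte genes were called without radial glia replicate 1. Antigen presentation genes were higher for 5 of 9 in LVW and 6 of 9 in SC, and for 6 in each adjusted over the list alone. B2m was lower, by 2.05 ± 0.50 in LVW and 1.49 ± 0.50 in SC, where it was not called with any 1 SC or radial glia array left out (adjusted p between 0.0591 and 0.129). H2-Ab1, a class II gene, was at least 8.56-fold higher in LVW and at least 5.59-fold in SC. The list test was called in both (adjusted p = 0.00687 and 0.00433). With an estimated correlation it held in SC (adjusted p = 0.0368) and was lost in LVW (adjusted p = 0.0561). Cholesterol synthesis genes were lower for 7 of 15 in LVW and 5 of 15 in SC, and for 7 and 5 adjusted over the list alone, with Nsdhl lower by 2.34 ± 0.46 in LVW. Without LVW replicate 2 or 3 the LVW count was 4, without radial glia replicate 2 or 3 it was 3, and without SC replicate 1 the SC count was 3. Both cholesterol calls (adjusted p = 0.0268 and 0.0119) were lost with an estimated correlation (adjusted p = 0.328 and 0.266).

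Markers of vessel walls, blood-derived cells and myelin moved beside these groups. Genes of endothelium and pericytes were lower for 11 of 18 in LVW and 13 of 18 in SC, and for 11 and 14 adjusted over the list alone. Acta2, Slco1c1 and Vwf were higher in LVW and Vwf in SC. Vwf was not called in LVW without LVW replicate 2 or 3 or radial glia replicate 1 or 2 (adjusted p between 0.061 and 0.118), or in SC without SC replicate 2 or radial glia replicate 1 or 2 (0.141 to 0.147). Kcnj8, a pericyte channel gene, was at least 90.4-fold lower in LVW and at least 85.1-fold lower in SC, and Rgs5 at least 46.9-fold and 44.2-fold. The list was called in both (adjusted p = 0.000129 and 2.58e-07). With an estimated correlation the SC call held (adjusted p = 0.0307) and the LVW call was lost (adjusted p = 0.0717). Without 1 radial glia array, 12 of these genes were tested. In LVW 7 were then lower without replicate 1 and 6 without replicate 2 or 3, and in SC 8 without replicate 1 and 7 without replicate 2 or 3. Laptm5, a leukocyte gene, was higher by 5.34 ± 0.72 in LVW and by 4.95 ± 0.72 in SC, while Coro1a, another, was lower in both (in LVW not called without LVW replicate 2 or 3 or any 1 radial glia array, adjusted p between 0.0553 and 0.0899). Mbp, a myelin gene, was higher by 6.94 ± 0.85 and 6.77 ± 0.85 (both genes were detected on 2 radial glia arrays), and Mobp at least 31.4-fold and 17.8-fold. Of 11 choroid plexus genes, 3 were lower and 2 higher in LVW, and 5 lower and 2 higher in SC, and the list was not called (adjusted p = 0.749 and 0.143). With any 1 radial glia array left out, 1 was lower in LVW. Of 9 genes of meninges, fibroblasts and Schwann cells, 4 were lower and 2 higher in LVW, and 3 lower and 1 higher in SC, and this list was not called (adjusted p = 0.0936 and 0.119). Col3a1 was at least 11.04-fold lower in LVW and 10.4-fold in SC. Without 1 radial glia array, 7 were tested, with 1 or 2 lower in LVW and 0 or 1 in SC.

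In all, 3473 genes differed between LVW and radial glia (1592 higher, 1881 lower) and 3033 between SC and radial glia (1413 higher, 1620 lower). With any 1 radial glia array left out, more genes were higher than lower in each, such as 1307 and 1279 in LVW and 1140 and 1112 in SC without replicate 1. With array weights the SC count was 4969. Median scaling moved the median change of all genes between SC and radial glia from -0.14 to -0.0017, and then 1549 genes were higher and 1324 lower. Which direction held more genes thus depended on the scaling in SC, and on the arrays kept in both groups. In LVW more genes were lower under each scaling and background correction tried. Further genes were among the largest differences. Got1l1, related to aspartate aminotransferase, was at least 303-fold higher in LVW and at least 159-fold in SC. Ramp1, a receptor component, was at least 139-fold higher in LVW, and Traf1, a signalling adaptor, at least 243-fold higher in SC. Ttr, the transthyretin gene of the choroid plexus list, was at least 251-fold lower in LVW and at least 236-fold lower in SC. Mmp9, a matrix protease gene, was at least 200-fold and 188-fold lower, and the transcription factor gene Tfap2c at least 115-fold and 109-fold. The imprinted gene Mest was at least 102-fold lower in SC.

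A further question was which differences from radial glia the 2 ependymal groups share. Both had the same 1046 genes higher and the same 1175 lower, and 17 genes went opposite ways. Independent lists of these sizes would share 236 and 320. The 2 comparisons use the same radial glia arrays, so part of the excess may come from those arrays, and 3 arrays cannot be divided into 2 sets of at least 2. In 50 simulations of unchanged groups against shared arrays, 0 genes were called in both, but hardly any calls can arise where no gene changes. That count thus does not show how many shared calls the radial glia arrays create. Across genes, which are not independent replicates, the changes correlated at r = 0.827 against 0.498 in the simulations, with a covariance of 2.87 against 0.147. The shared genes include 33 cilia genes higher in both, 10 ependymal markers higher, 27 cell cycle genes lower and 11 forebrain factors lower. The endothelium and pericyte list also had 11 genes lower in both. With SC replicate 1 alone in its group the shared count was 1392 in place of 2221.

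Neurospheres were compared with SC ependymal cells to ask how the cultured cells differ from the freshly sorted ones. The neurospheres were not sorted. The SC arrays also held signal of myelin genes and of some of the 5 leukocyte genes tested, of 17 named on the array. A change in the mix of cells thus cannot be told apart from a change within ependymal cells. Cilia genes were lower almost throughout: 34 of 38 were lower, and 36 adjusted over the list alone. Tekt1, which encodes a ciliary filament protein, fell by 7.94 ± 0.45 (SE, n = 3 per group; detected on 1 neurosphere array), and Pifo was at least 79.6-fold lower. The list median was -4.98, and -4.75 with bounds (adjusted p = 9.18e-29), and the call held with an estimated correlation (adjusted p = 0.017). The largest falls of all were in 5 more genes of cilia and sperm tails and in Traf1. Odf3b was at least 388-fold lower, Cfap65 at least 344-fold and Cfap161 at least 165-fold. Traf1 was at least 232-fold lower. Among ependymal markers 7 of 17 were lower, and 7 adjusted over the list alone. Mia fell by 8.22 ± 0.60 (detected on 2 neurosphere arrays), Clu fell by 4.17 ± 0.45, and Trp73, a regulator of the multiciliated state, was at least 30.5-fold lower. The marker list call (adjusted p = 0.000305) was lost with an estimated correlation (adjusted p = 0.109).

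Genes of proliferation and of progenitors were higher in neurospheres. Of 33 cell cycle genes, 18 were higher, and 20 adjusted over the list alone. Cdc6, which licenses DNA replication, was higher by 3.67 ± 0.53, and Aurkb, a mitotic kinase gene, at least 5.57-fold. Without neurosphere replicate 2, 9 cell cycle genes were called. The list median was 1.67 (adjusted p = 2.49e-06), and its call was lost with an estimated correlation (adjusted p = 0.307). Stem and progenitor genes were higher for 11 of 22, and for 12 adjusted over the list alone, while Id4 and Pax6 were lower. Egfr, the receptor for epidermal growth factor, was higher by 5.22 ± 0.43 and the matrix gene Tnc at least 12.9-fold. Id4 was at least 19.01-fold lower while Id3 was higher by 4.15 ± 0.37. The list median was 1.57, and 0.86 with bounds, and its call (adjusted p = 0.00736) was also lost with an estimated correlation (adjusted p = 0.109). Olig2, a transcription factor of ventral progenitors and the oligodendrocyte lineage, was higher by 6.94 ± 0.49, and Nkx2-2 at least 6.03-fold. The heparan sulfate enzyme gene Hs3st2 was at least 136-fold higher and the synaptic gene Sez6l at least 64.3-fold. Ptn, a growth factor gene, was higher by 7.19 ± 0.63. SC detected Cdc6, Olig2 and Ptn on 1 array and Egfr and Id3 on 2.

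Regional genes were partly kept in culture. Against radial glia, 15 of 20 Hox genes were higher in neurospheres, and 17 adjusted over the list alone. Against SC ependymal cells the Hox list was not called (adjusted p = 0.112). Within it, Hoxd10 (-3.05 ± 0.40), Hoxb13 (-2.65 ± 0.32) and Hoxb5 (-1.85 ± 0.24) were lower, Hoxd3 was at least 3.50-fold lower, and Hoxb9, Hoxa9 and Hoxc4 were higher. The neural tube patterning list had a negative median (-0.34) and a positive mean (0.18), and was not called (adjusted p = 0.924). Cholesterol synthesis genes were higher for 7 of 15, and adjusted over the list alone 11 were higher and 1 lower, with Cyp51 higher by 4.51 ± 0.71. Without SC replicate 1 or 2, or without neurosphere replicate 2, 4 were called. The cholesterol call (adjusted p = 0.00515) was lost with an estimated correlation (adjusted p = 0.307). Immediate early and stress genes were lower for 6 of 16, and 6 adjusted over the list alone, while Ier3 was higher. Atf3 fell by 3.68 ± 0.46, and Ccn1 was at least 6.73-fold lower. Of 5 leukocyte genes tested, Laptm5 fell by 5.84 ± 0.72, C1qb was at least 2.45-fold and Ly86 at least 2.20-fold lower, and Ly86 was not called with SC replicate 1 alone in its group (adjusted p = 0.0614). The myelin gene Mbp was at least 99.5-fold lower. Neurospheres detected Hoxd10, Hoxb13, Atf3 and Laptm5 on 1 array. The calls of the immediate early (adjusted p = 0.00717) and leukocyte lists (0.0361) were lost with an estimated correlation (adjusted p = 0.144 for each). In all, 1473 genes were higher and 1401 lower. With median scaling 1227 were higher and 1398 lower, and with any 1 array of these groups left out more were lower than higher, so neither direction prevailed throughout. For a neurosphere array left out, the filter also drops genes detected on those 3 arrays alone, which favours lower genes.

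These changes were then set beside the difference between radial glia and LVW ependymal cells, which shares no array with them. In culture 553 genes were higher that were also higher in radial glia than in LVW, and 803 were lower that were also lower in radial glia. Opposite directions were called for 146 genes. Independent lists would share 291 and 234. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.530. The next sets were chosen partly on the SC arrays with which neurospheres are then compared, which favours changes back in culture, and no value without change was computed for them. Of the 1046 genes higher in both ependymal groups than in radial glia, 747 were lower in neurospheres than in SC ependymal cells, and 15 were higher. Of the 1175 genes lower in both, 480 were higher in neurospheres, and 24 were lower. All 33 cilia genes among the first set were lower in culture, as were 6 of 10 ependymal markers and 1 of 7 astrocyte genes.

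**Figure D3:**
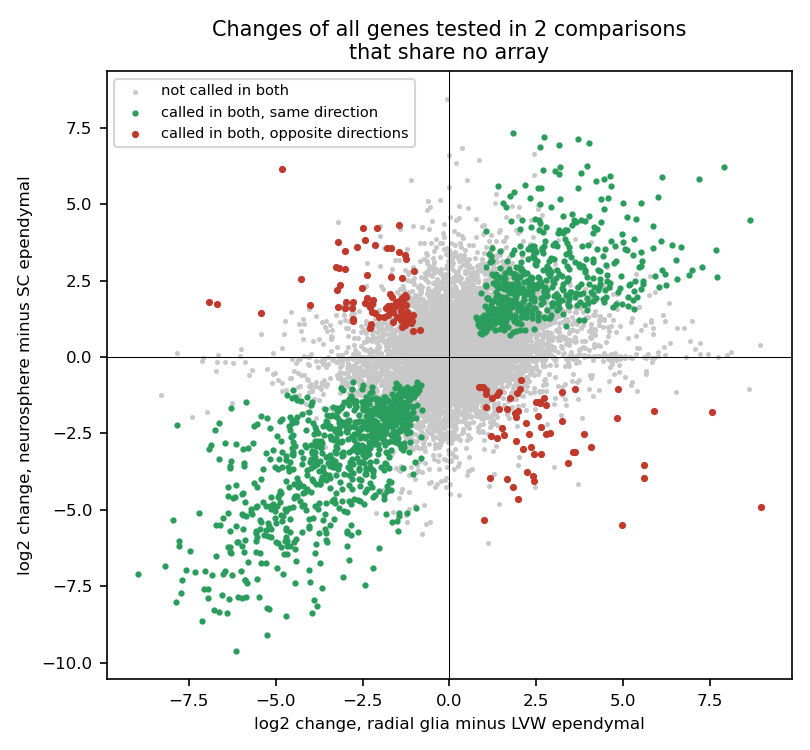
Log2 change of each gene in neurospheres against SC ependymal cells (vertical axis) and in radial glia against LVW ependymal cells (horizontal axis). Green points are the 553 and 803 genes called in the same direction in both, and red points the 146 called in opposite directions.

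The last comparison asked how neurospheres differ from radial glia. The groups differ in region of origin, age and culture. Neurospheres had higher Hox and astrocyte genes and lower forebrain, Notch and vessel wall genes. Hoxa7 was at least 177-fold higher (n = 3 per group). Of 16 astrocyte genes 11 were higher, and 11 adjusted over the list alone, with Ntsr2 at least 9.08-fold higher. Acsbg1, a lipid metabolism gene, was higher by 3.44 ± 0.62 (SE). Forebrain factors were lower for 14 of 17, and 15 adjusted over the list alone, with Otx1 at least 112-fold lower. The list medians were 3.77 for Hox genes, 2.76 for astrocyte genes and -3.44 for forebrain factors (2.89, 2.47 and -2.47 with bounds). All 3 calls (adjusted p = 5.3e-17, 1.13e-07 and 2.35e-13) held with an estimated correlation (adjusted p = 0.00313, 0.0421 and 0.000774). Olig2 was higher by 4.84 ± 0.49 and the Notch ligand gene Dner by 3.78 ± 0.44. With any 1 radial glia array left out, 11 forebrain factors were tested and 8 were lower.

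Cilia genes were lower in neurospheres than in radial glia for 16 of 38, and 17 adjusted over the list alone. Tekt1 fell by 4.07 ± 0.45. Without radial glia replicate 3, 9 were called. The cilia call (adjusted p = 9e-05) was lost with an estimated correlation (adjusted p = 0.177). Cell cycle genes were lower for 8 of 33, and 8 adjusted over the list alone, with Birc5 lower by 2.64 ± 0.46 and E2f1 by 2.18 ± 0.46. With any 1 radial glia array left out or with neurosphere replicate 1 left out, 5 were called. This list call (adjusted p = 0.000213) was lost with an estimated correlation (adjusted p = 0.336). Notch pathway genes were lower for 8 of 16, and 9 adjusted over the list alone, with Heyl, also a mural cell gene, at least 24.2-fold lower. With any 1 radial glia array left out 5 were lower. Immediate early genes were lower for 7 of 16, and 10 adjusted over the list alone, and the change of Klf2 was -4.24 ± 0.56. Ier3 was higher (1.36 ± 0.38), but was not called with any 1 radial glia array or neurosphere replicate 1 or 2 left out (adjusted p between 0.0587 and 0.107). The Notch and immediate early calls (adjusted p = 0.000137 and 0.000126) held with an estimated correlation (adjusted p = 0.0142 and 0.0382). Antigen presentation genes had 1 called member, H2-T23 (2.81 ± 0.37), and 4 adjusted over the list alone. Neurospheres detected Tekt1 and Klf2 on 1 array and Birc5 on 2. The antigen presentation list was called (adjusted p = 0.00497) and held with an estimated correlation (adjusted p = 0.0421). Without neurosphere replicate 3 it had 2 called members.

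Markers of other cells went both ways in neurospheres against radial glia. Beside the higher astrocyte genes, 4 of 15 oligodendrocyte lineage genes were higher and 0 lower, and 4 higher and 1 lower adjusted over the list alone, while this list was not called (adjusted p = 0.0967). Of 18 endothelial and pericyte genes 12 were lower, and 13 adjusted over the list alone, with Kcnj8 at least 104-fold and Pdgfrb at least 70.0-fold lower. Without radial glia replicate 2 or 3, 12 were tested and 7 were lower. Of 11 choroid plexus genes 6 were lower, and 8 adjusted over the list alone. Among them, Ttr was at least 289-fold lower and Clic6 fell by 6.51 ± 0.72. Both lists were called (adjusted p = 6.79e-11 and 2.32e-05) and held with an estimated correlation (adjusted p = 0.0142 and 0.0421). The lists of neurons (7 of 18 lower, 2 higher), of meninges, fibroblasts and Schwann cells (5 of 9 lower, 1 higher) and of the Wnt pathway (11 of 24 lower, 5 higher) were called lower (adjusted p = 0.00308, 0.00308 and 0.0256), and all 3 calls were lost with an estimated correlation (adjusted p = 0.0594, 0.0609 and 0.177). With 1 radial glia array left out, 4 or 5 of 16 neuronal genes, 1 to 3 of 7 meningeal genes and 5 to 7 of 21 Wnt genes were lower. The 2 higher neuronal genes were Snap25 and Gad2, and neither was called without radial glia replicate 1 or 3 or neurosphere replicate 1. In all, 879 genes were higher and 1054 lower. The count was 1147 without radial glia replicate 1, 1160 without radial glia replicate 3 and 1191 without neurosphere replicate 1, and 4123 with array weights. The largest increases included Camk2b, a calcium-dependent kinase gene, at least 272-fold, and the potassium channel gene Kcnc4, at least 85.5-fold. The Wnt inhibitor gene Sfrp1 fell by 6.58 ± 0.56, and like Clic6 it was detected on 1 neurosphere array.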

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

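The averaging of neurosphere replicates 1 and 2, and the setting that leaves out SC replicates 2 and 3, were tests chosen only after the results were seen; the other alternatives were planned.

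No called gene among those named reversed under any alternative run. The list test was rerun only with an estimated correlation, which cannot alter a direction, the authors' values and median scaling. No called gene list reversed in these. The named comparisons of a gene that were called numbered 395. Apart from leaving out arrays, the planned settings called 362 to 395, newly called ones included, fewest without background correction. In that setting 35 of the 395 lost their call and 2 other comparisons gained one. Leaving out 1 array gave at least 375, but this counts as called the comparisons that the filter then left untested, and any newly called. The lists called with camera numbered 50, and 24 with an estimated correlation. That test uses each list's own correlation in place of 0.01. Median scaling gave 54.

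The count for SC against LVW was 766 in the common fit and 292 in a fit to the 6 arrays alone. Leaving out 1 array gave 475 to 995, lowest without SC replicate 3 and highest without LVW replicate 3. Array weights raised SC against radial glia from 3033 to 4969, neurospheres against SC from 2874 to 4243 and neurospheres against radial glia from 1933 to 4123. Causes were not tested. Apart from leaving out 1 array at a time, the planned settings gave 3125 to 3874 genes for LVW against radial glia. Their lowest counts for SC against radial glia, neurospheres against SC and neurospheres against radial glia were 2790, 2582 and 1642.

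Leaving out SC replicates 2 and 3, whose myelin genes stand apart, kept a single SC array, which is assumed to vary like the other groups. SC against LVW then gave 228 genes, SC against radial glia 1666 and neurospheres against SC 1492. The genes shared by both ependymal groups against radial glia were 1392, and those that moved together in culture and in radial glia were 855. The smaller number of SC arrays is part of this setting's construction.

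Leaving out 1 array at a time gave 2586 to 3603 genes for LVW against radial glia, 2250 to 2539 for SC against radial glia and 1990 to 3276 for neurospheres against SC. Neurospheres against radial glia gave 1147 to 2828, highest without neurosphere replicate 3. The shared ependymal genes were 1614 to 2286, and the genes moving together in culture and radial glia 1108 to 1485. Neurosphere replicates 1 and 2 were closer (r = 0.973) than any other pair, though radial glia replicates 1 and 3 came near (0.968). The labels' protocols call the arrays of a group independent, and closeness alone cannot decide whether these 2 are. With both averaged, neurospheres gave 2143 genes against SC and 1361 against radial glia.

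Same-numbered arrays of different groups were not closer to each other than others. Of 18 such pairs, 3 had residual correlations over 0.1, in a range of -0.229 to 0.322, beside -0.304 to 0.289 for other pairs. With the replicate number as a block the counts were 592, 3267, 2849, 2663 and 1739. A block for the slide was not run, as the file names no slides.

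Signal over background limits the size of many changes. The lower group was below detection for 242 called genes in SC against LVW, 991 in LVW and 934 in SC against radial glia, 773 in neurospheres against SC and 501 in neurospheres against radial glia.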

Other observations

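The gene family, imprinted gene, ribosomal protein, mural, endothelial, normalization, myelin, cilia, oligodendrocyte progenitor, linked cell cycle gene, neuroblast and neurosphere array tests below were chosen only after the results were seen; the second cell cycle list and the other splits of the arrays were set before their results were seen.

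Imprinted genes, many of which act in embryonic growth, were in part higher in radial glia than in the other groups. Of 18 tested from a list of 29, 10 were lower in LVW ependymal cells, 8 in SC ependymal cells and 10 in neurospheres, with median changes of -2.15, -1.59 and -1.98 (-2.07, -1.34 and -1.76 with bounds). In each ependymal group 2 were higher. The lower bounds of the intervals of random lists of like mean expression were -0.90, -0.76 and -0.56, and camera with an estimated correlation gave unadjusted p = 0.00603, 0.00864 and 0.00115. Igf2 fell by 8.63 ± 0.91 in LVW (SE, n = 3 per group), where it was detected on 1 array, and Mest was at least 102-fold lower in SC. Igf2 is also in the choroid plexus list, and mural cell genes were higher in the same radial glia arrays. The cells behind the imprinted changes thus stay open. Ribosomal protein genes were also lower in the adult cells, 29 of 45 in LVW (median -1.21) and 20 of 45 in SC (median -0.94), but these genes are linked, and camera with an estimated correlation gave unadjusted p = 0.0652 and 0.0995. The directions of the imprinted medians against radial glia and of these ribosomal medians were the same under each scaling tried.

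Families of genes that share a name stem were tested for called genes. Among 103 families of at least 10 genes, 23 one-sided Fisher's exact tests passed after adjustment. Of 19 Cfap genes, 17 were higher than radial glia in LVW (adjusted p = 7.22e-10) and 17 in SC (adjusted p = 9.8e-11), and 16 were lower in neurospheres than in SC (adjusted p = 2.86e-09). Of 14 Ift genes, which carry cargo along cilia, 12, 10 and 12 did the same. Each of these 2 families has 1 gene in the fixed lists, and without it 16 of 18, 16 of 18 and 15 of 18 Cfap genes (highest adjusted p = 1.15e-08) and 11, 9 and 11 of 13 Ift genes (highest adjusted p = 0.000546) were called. Of 19 Col genes, which encode collagens, 14 were lower in neurospheres than in radial glia (adjusted p = 2.67e-08) and 10 in LVW (adjusted p = 0.0363); without the 3 collagen genes in the fixed lists the adjusted p were 3.71e-06 and 0.137. With an estimated correlation camera gave unadjusted p = 0.0139 and 0.109. The 14 include collagens of fibroblasts and vessel walls such as Col3a1, and the list of mural cell genes was also lower in neurospheres than in radial glia (21 of 25, median -4.57), so the cells behind the collagen change stay open. Of 14 Nup genes of the nuclear pore, 9 were lower in LVW than in radial glia (adjusted p = 0.0117). Genes of a family are not independent of each other.

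A list of neuroblast and transit amplifying genes, 14 of whose 22 genes are in the fixed lists, had a median of -0.44 in SC against LVW over 16 tested genes. With bounds it was 0, and its bootstrap interval was -1.58 to 0.13, with 2 genes higher and 3 lower. Neurosphere replicate 3, which had the most detected probes, differed from the other two most in the Wnt list, with a median of -0.58 at percentile 0.21 of random lists. The Hox list, with -0.51 at percentile 1.88, was the only other one outside its random lists.

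Vessel wall genes stood out in the sorted radial glia: a list of 32 mural cell genes, 9 of them in the fixed lists, had median changes of -5.56 in LVW and -5.24 in SC against radial glia, with 22 of 25 tested genes lower in each (unadjusted p = 0.0139 and 0.0127 with an estimated correlation). Without the shared genes the medians were -4.60 and -4.90, and with bounds those of the whole list were -4.60 and -4.31. The probe filter admits a gene detected on the 3 radial glia arrays alone, as Kcnj8 and Rgs5 were. Such a gene could hardly be called higher in another group, so the counts and medians favour radial glia. The same limit holds for the other lists set against radial glia. Kcnj8, Pdgfrb and Rgs5 had mean log2 levels of 12.36, 11.79 and 11.42 in radial glia, and the smaller excess of the list there, 5.24, is consistent with mural cells among the sorted cells, although the CD133 gate would remove cells without CD133 and expression by radial glia themselves was not tested. The lowest excess over 3 other ways of processing was 3.56, which argues against background correction or normalization. Endothelial cells, which the CD34 gate would remove where they carry CD34, stay open. A list of 32 endothelial genes (17 in the fixed lists) had 19 tested. Against LVW its excess in radial glia was 1.20 (0.89 with bounds), with 9 genes lower in LVW and 2 higher. The change there had an interval of -2.38 to 0.31. In SC the change was -2.05 (-0.81 with bounds), with an interval of -2.37 to -1.38, and 10 genes were lower and 1 higher. Camera with an estimated correlation gave unadjusted p = 0.178 for LVW and 0.0381 for SC. Esam was at 11.95 to 12.75 and Emcn at 11.07 to 12.11 in radial glia, but Cldn5 at 5.16 to 5.98 and Kdr at 5.71 to 6.04. The endothelial genes Pecam1, Cdh5 and Tie1 were on the array, but no probe of theirs passed the detection filter. None of their probes was thus detected on all 3 radial glia arrays, and the medians, over tested genes only, leave these genes out.

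Myelin genes set the SC ependymal arrays apart from each other. A list of 26 myelin genes, 13 of them in the fixed lists, was higher on replicates 2 and 3 than on replicate 1 by a median of 2.63 over 14 tested genes, and by 1.59 over the 7 tested genes outside those lists, where random lists of like expression had upper bounds of 0.38 and 0.64. Mbp was at 9.78 on replicate 1 and 13.56 and 13.55 on replicates 2 and 3 (11.83 to 13.27 on the LVW arrays) and Cldn11 at 4.58, 11.65 and 12.60, which may come from oligodendrocyte RNA in those arrays, although the CD133 and CD24 gates would remove oligodendrocytes that lack these antigens. A difference in array or RNA quality as the whole cause is argued against, since cilia genes differed by a median of -0.075 (interval -0.17 to 0.027), but 16 astrocyte genes (0.40) and 2 red blood cell genes (1.62) were also above the upper bounds of random lists, 0.26 and 1.55. No biological explanation was tested, as the 3 arrays belong to 1 group.

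Cell cycle genes had a median of 0.69 in SC against LVW ependymal cells, 0.30 with bounds, and what lies behind it stays open. A second list of 81 cell cycle genes, with 0 in the fixed lists, had a median of 0.47 over 57 tested (interval 0.11 to 0.84), above 99.98% of random lists, with 9 genes called higher. Chance is not argued against, since random lists hold unlinked genes, members of these lists correlate at 0.29 and 0.23, the test with that correlation gave unadjusted p = 0.241 and 0.281, and the second median was 0.11 with bounds. Oligodendrocyte progenitors as the source also stay open: the median of their 19 genes, 6 of them in the fixed lists, was -0.065 over members that went both ways, with an interval of -0.80 to 0.58. Dividing cells of another type, and a difference between the regions, may each explain the difference and were not tested.

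In each comparison, 6 arrays can be split into groups of 3 in 10 ways, which are too few for a share under 0.05. As many genes as in the real split came from 1 split, the real one, in each of the 5 comparisons. SC against LVW called 766 genes with a highest other split of 12, and LVW against radial glia 3473 with a highest other of 1. SC against radial glia called 3033, neurospheres against SC 2874 and neurospheres against radial glia 1933, with a highest other of 0 each.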
